A study of Drosophila melanogaster with 31 samples.

How the data were processed

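RNA-seq counts of 18 libraries were analysed, 6 groups of 3, out of 31 samples in the series; the 13 ChIP-nexus samples were not analysed here. Per the labels, each library came from hand-dissected wing discs of pooled larvae, in which mitotic recombination gave clones of the stated genotype in a Minute background, and mRNA libraries were made with a TruSeq kit. The authors deposited 1 table of raw read counts per gene for all 18 libraries; per the submitters' processing notes the tools were Bowtie2, TopHat2, HTSeq and DESeq2 on the dm6 build, and their versions, roles and strand setting are not given in the sources used here. The table held 17373 genes, of which 2937 had 0 counts in every library. Gene symbols were looked up in a reference gene table of release 6 (dm6): 12766 matched by symbol, 4387 by synonym and 220 did not match. Coordinates are those of release 6. Totals ranged from 14201662 to 26217144 counts per library.

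Groups and replicate numbers were taken from the labels. Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, all 18 libraries in 1 fit with a coefficient per group), which left 9004 genes, and p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. Standard errors were derived from the F statistic. The common biological coefficient of variation was 0.185 and the prior degrees of freedom 3.5. CPM values were computed here from the deposited counts with TMM-scaled library sizes and are means ± SD of 3 libraries. The 9 comparisons were cic, wts and cic wts against control at day 5, cic wts against wts on each day, day 9 against day 5 in wts and in cic wts discs, and the interactions of cic with wts at day 5 and of cic with day. No pair of replicates held identical values, and their chi-square per degree of freedom ranged from 11.1 to 64.

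Altogether 32 gene lists, fixed before the data were examined, were tested with camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over all lists and comparisons; lists with under 3 tested genes have values only. Camera was repeated with a correlation estimated per list, and fry was run beside it. Lists are given with the count over all genes tested and that adjusted over the list alone. Camera made 102 calls among 279 tests of a list in a comparison, and 0 of them held with an estimated correlation, where fry made 60; the adjusted p values with an estimated correlation stand beside each call, or as a range where calls are listed together.

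The genes that could be named were fixed by a rule before the data were examined: cic and wts; the 10 largest rises and the 10 largest falls past the threshold without overlap between libraries and with at least 5 CPM in a compared group; up to 4 members of each list per comparison; and all members of the Yki/Sd and the Ras/EGFR and Cic target lists. The 299 results followed through the alternatives are a selection from those genes that was made after their values were seen, and genes whose call rested on 1 library were partly left out of the text, so the share of robust calls among the genes named is not that among all genes called. Alternatives fixed beforehand were RLE size factors, total-count scaling, no filter on low counts, a DESeq2 1.42.0 Wald test, the replicate number as a block, only the libraries compared in the fit, and leaving out each library in turn. Among the alternatives, 2 were added after the data were seen: the roX level of each library as a covariate, and control day 5 replicate 3 with cic wts day 5 replicate 1 left out together. The procedure was tested on simulated counts for 9004 genes: edgeR recovered 59.7% of genes changed 1.5 times, 71.6% changed 2 times and 81.8% changed 4 times in cic against control, and 23.9%, 67.2% and 74.2% of these sizes for the interaction of cic with wts. Of the simulated calls, unchanged genes made up 1.39% with edgeR and 10.8% with DESeq2 in cic against control, 4.35% and 11.4% for the interaction, and 5.8% and 14.4% in cic wts against wts at day 9.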

Results

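The series profiled wing imaginal discs, the larval epithelia that give rise to the adult wing and notum, from Drosophila melanogaster larvae. The discs were mosaic: recombination driven in the disc produced patches of homozygous mutant cells beside slow-growing cells heterozygous for a Minute mutation. RNA was sequenced from 6 groups of 3 libraries each. At day 5 these were control clones, clones mutant for capicua (cic), clones mutant for warts (wts) and clones mutant for both (cic wts). At day 9 the groups were wts and cic wts, and no control or cic group of that age was analysed here. Capicua is a repressor of genes that Ras/EGFR signalling turns on, and Warts is the Hippo pathway kinase that restrains the co-activator Yorkie. The title of the series poses the question of how Hippo signalling alters the transcriptional response to Ras, so the effect of losing cic was compared between the control and the wts backgrounds. Libraries held between 14201662 and 26217144 counts, and 9004 of 17373 genes had enough counts to be tested. Each library was a pool of discs from several larvae; the labels number the replicates without saying whether the pools were raised separately, so p-values measure the spread between these pools.

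The first principal component, with 34.1% of the variance, separated the 6 control and cic libraries from the 12 wts and cic wts libraries. The second, with 16.8%, separated day 5 from day 9 among those 12. Transcripts of other larval tissues differed between libraries of the same group. The salivary glue gene Sgs3 stood at 0.978, 97.5 and 2564 CPM (counts scaled to library size) in control replicates 1, 2 and 3, and at no more than 3.91 CPM in any library of the other groups. The hemocyte genes Hml and PPO1 stood at 279 and 509.6 CPM in cic wts day 5 replicate 1, against 10.8 and 7.04 CPM in replicate 2. The fat body storage protein gene Lsp1beta reached 382 CPM in cic wts day 5 replicate 2 and 115 CPM in wts day 9 replicate 2. The dosage compensation RNA roX1, which is made in males, averaged 404 ± 178 CPM (mean ± SD, n = 3 in this and all other groups) in control, 263 ± 147 in cic, 638 ± 74.0 in wts and 738 ± 308 in cic wts discs at day 5.

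The mutated genes were examined in every library. The cic transcript (3R 20252770 to 20303942, release 6 coordinates) measured 569, 658 and 533 CPM in control, 578, 396 and 426 CPM in cic, 694, 609 and 637 CPM in wts and 454, 489.7 and 449.9 CPM in cic wts discs at day 5. At day 9 it measured 686, 748 and 705 CPM in wts and 516, 509 and 469 CPM in cic wts discs. Against the control, its log2 fold change in cic discs was -0.33 ± 0.12 (± standard error; adjusted p = 0.25, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as for all genes that follow) and did not pass. Cic replicate 1 lay within the range of the controls. Against wts discs, cic fell in cic wts discs by 0.48 at day 5 (adjusted p = 0.033) and by 0.52 at day 9 (adjusted p = 0.012). The call at day 5 was lost without any 1 of the 6 libraries compared (adjusted p from 0.06 to 0.18), and that at day 9 without cic wts day 9 replicate 3 (-0.48, adjusted p = 0.056).

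The wts transcript (3R 30789625 to 30806619) was higher, not lower, in wts mutant discs. It measured 99.3, 106 and 95 CPM in control, 109, 99.0 and 109.9 CPM in cic, 214, 210.2 and 185 CPM in wts and 162, 174 and 207 CPM in cic wts discs at day 5, and 273, 258 and 278 CPM and 224, 224 and 227 CPM in wts and cic wts discs at day 9. It rose by 1.02 ± 0.08 (adjusted p = 1.1e-06) in wts discs and by 0.85 ± 0.08 (adjusted p = 5.1e-06) in cic wts discs at day 5. The deposited values count reads over the whole gene, and a mutant allele that is still transcribed contributes to them, so neither transcript level alone identifies the genotype of a library.

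Loss of cic alone, in cic against control discs at day 5, was compared to find which genes respond where Hippo signalling is intact. The EGFR antagonist argos (aos, 3L 16470386 to 16483650) rose by 0.91 ± 0.11 (adjusted p = 0.00045), from 29.6 ± 2.51 to 55.6 ± 10.3 CPM. The ETS transcription factor gene pointed (pnt, 3R 23290231 to 23346167) rose by 0.46 ± 0.11 (adjusted p = 0.037). The FGF ligand gene branchless (bnl) rose by 1.38 ± 0.25 (adjusted p = 0.0095) and the initiator caspase gene Dronc by 0.65 ± 0.12 (adjusted p = 0.008), while the mitotic cyclin gene CycB3 fell by 0.32 (adjusted p = 0.0041). Values of other genes of the pathway did not pass: sprouty (sty, 3L 3401153 to 3424935), an inhibitor of receptor tyrosine kinase signalling, was at 0.24 ± 0.14 (adjusted p = 0.59) and the ERK phosphatase gene Mkp3 at 0.34 ± 0.12 (adjusted p = 0.27). Of the 15 Ras/EGFR and Cic target genes, 2 rose, 0 fell and 13 did not pass (2 and 1 adjusted over the list alone). Ras/EGFR and Cic target genes had an upward camera adjusted p = 0.0314, and adjusted p = 0.537 with an estimated correlation. In fits that lacked 1 library, pnt lost its call in 5 of 6 (adjusted p from 0.068 to 0.16), and bnl (1.15, adjusted p = 0.062) and Dronc (0.58, adjusted p = 0.054) lost theirs without cic replicate 2.

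Of the genes of the detoxification and stress response known from Minute cells, GstE6 rose in cic discs by 2.32 ± 0.38 (adjusted p = 0.0041) and CG6272, the partner of Xrp1, by 0.99 ± 0.17 (adjusted p = 0.0057). Of the 13 measured genes of this response, 4 rose, 0 fell and 9 did not pass (7 and 1 adjusted over the list alone, upward camera adjusted p = 9.6e-05, and adjusted p = 0.391 with an estimated correlation). The 13 apoptosis genes included 2 that rose, Dronc and the inhibitor of apoptosis Diap1 (0.27 ± 0.06), and 0 that fell in edgeR (2 and 0 adjusted over the list alone, camera adjusted p = 0.132). Diap1 lost its call in 5 of 6 fits that lacked 1 library (adjusted p from 0.057 to 0.24). Of the 33 cell cycle genes, 0 rose, 1 fell and 32 did not pass (0 and 1 adjusted over the list alone). Cell cycle genes had a downward camera adjusted p = 0.000296, and adjusted p = 0.485 with an estimated correlation. Of the 16 cuticle genes, 0 rose, 1 fell and 15 did not pass (0 and 1 adjusted over the list alone). Cuticle genes had a downward camera adjusted p = 0.017, and adjusted p = 0.485 with an estimated correlation. Salivary gland transcripts moved with this comparison: all 7 measured markers fell (0 and 7 adjusted over the list alone, downward camera adjusted p = 5.8e-05, and adjusted p = 0.485 with an estimated correlation). Sgs3 averaged 888 ± 1453 CPM in control and 2.18 ± 1.5 CPM in cic discs, and its call was lost in 4 of 6 fits that lacked 1 library (adjusted p from 0.06 to 0.089). Of the 13 differentiated muscle genes, 0 rose, 1 fell and 12 did not pass (0 and 1 adjusted over the list alone). Differentiated muscle genes had a downward camera adjusted p = 0.00125, and adjusted p = 0.619 with an estimated correlation. The roX RNAs were at -0.62 ± 0.42 for roX1 and -0.70 ± 0.43 for roX2, without a call (0 and 0 of 2 adjusted over the list alone).

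The cell adhesion gene Dscam4 (3L, from 8238647) fell by 5.69 ± 0.17 (adjusted p = 6.5e-12), to 0.968 ± 0.3 CPM against 49.8 ± 4.05 in control and 69.4 ± 6.47 in cic wts discs. The noncoding gene CR43144 (2L, from 21657625) rose by 3.56 ± 0.20 (adjusted p = 4.6e-08) and Snap25 (3L, from 24074180), a gene of synaptic vesicle fusion, by 3.15 ± 0.28 (adjusted p = 1.5e-05). Whether counting used the strand is not given in the sources used here, so reads of overlapping genes such as noncoding ones, and of close paralogs such as the GstE genes, may be assigned to the wrong member. CG4362, which lies next to cic (3R, from 20306216), rose by 3.61 ± 0.58 (adjusted p = 0.0039) from 1.91 ± 2.16 CPM in control, and measured 0.962 ± 0.314 in cic wts discs. Its interaction of cic with wts was -3.47 ± 0.84 (adjusted p = 0.047), a call lost in 10 of 12 fits that lacked 1 library (adjusted p from 0.053 to 0.13), with total-count scaling (adjusted p = 0.052) and with only day 5 libraries in the fit (adjusted p = 0.14). The receptor gene mthl8 stood at 11.5 ± 5.98 CPM in cic discs and at 0 counts in every library of the other groups, cic wts included. Falls were measured for pastrel (pst; -1.25 ± 0.13, adjusted p = 5.5e-05), CG5455 (-1.39 ± 0.15) and the protease gene Tequila (-1.02 ± 0.16), which measured 36.8 ± 2.59, 6.83 ± 0.751 and 8.81 ± 0.873 CPM in cic and 72.7 ± 4.81, 16.1 ± 2.03 and 13.5 ± 3.10 CPM in cic wts discs. In all, 86 genes rose and 61 fell, 147 of 9004 tested. The count was 61 without cic replicate 2 and 71 without control replicate 2, 251 with DESeq2, 91 with the roX level as a covariate and 19 when only the 6 libraries compared entered the fit.

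**Figure D1:**
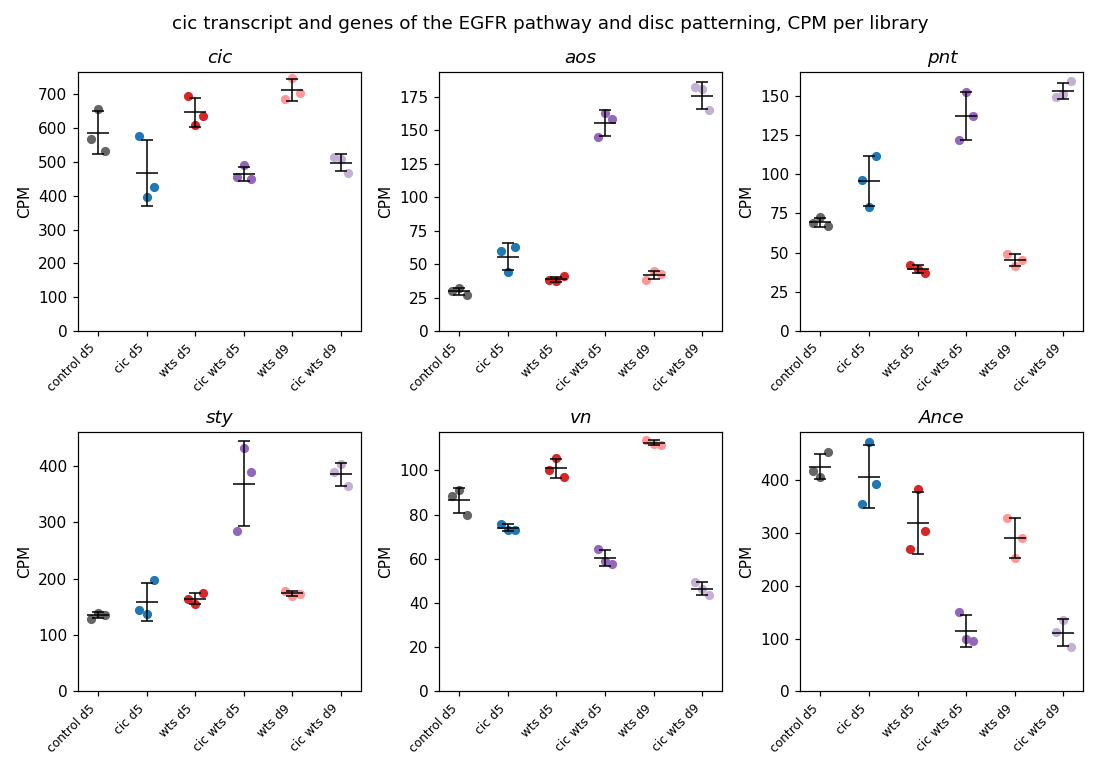
CPM on linear axes for cic, aos, pnt, sty, vn and Ance in each of the 18 libraries (points), with the mean and SD of each group of 3 (bars). The aos transcript averaged 29.6 CPM in control, 55.6 in cic, 38.8 in wts and 155 in cic wts discs at day 5.

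Loss of wts alone, in wts against control discs at day 5, was compared to find the genes that respond when Yorkie is released. The relaxin-like hormone gene Ilp8, whose product delays pupariation, rose by 5.84 ± 0.49 (adjusted p = 1.5e-06), from 0.821 ± 0.905 to 49.0 ± 3.19 CPM. The upstream Hippo genes kibra and expanded (ex), which Yorkie induces in a feedback loop, rose by 1.67 ± 0.11 (adjusted p = 2.5e-07) and 1.44 ± 0.10 (adjusted p = 2.8e-07). The JAK/STAT ligand gene outstretched (os, also unpaired) rose by 1.04 ± 0.12 (adjusted p = 3.4e-05), and chinmo, a target of that pathway, by 1.84 ± 0.36 (adjusted p = 0.003). Smaller rises were measured for the growth regulator Myc (dm; 0.66 ± 0.09), cyclin E (CycE; 0.44 ± 0.10), Diap1 (0.41 ± 0.06) and the glypican gene dally (0.39 ± 0.08), and the wing selector gene vestigial (vg) fell by 0.45 (adjusted p = 0.001). Of the 20 Yki/Sd target genes, 11 rose, 2 fell and 7 did not pass (11 and 2 adjusted over the list alone). Yki/Sd target genes had an upward camera adjusted p = 0.000146, and adjusted p = 0.443 with an estimated correlation. Of the 17 Hippo pathway components, 4 rose, 1 fell and 12 did not pass (5 and 2 adjusted over the list alone, camera adjusted p = 0.0854). Of the 11 JAK/STAT ligands and targets, 4 rose, 0 fell and 7 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.178). The ligand gene upd3 rose by 1.27 ± 0.32 (adjusted p = 0.014) and lost the call without wts replicate 3 (1.23, adjusted p = 0.052).

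Among genes of the Ras/EGFR pathway, the phosphatase gene string (stg), which drives entry into mitosis, rose by 1.74 ± 0.41 (adjusted p = 0.0097), while pnt fell by 0.81 (adjusted p = 0.00015) and the protease gene rhomboid (rho) by 1.53 (adjusted p = 0.0058). Of the 15 Ras/EGFR and Cic target genes, 4 rose, 3 fell and 8 did not pass (4 and 4 adjusted over the list alone, camera adjusted p = 0.719). Of the Notch target genes of the Enhancer of split complex, E(spl)m2-BFM fell by 1.19 (adjusted p = 7e-04) and E(spl)mgamma-HLH by 1.31 (adjusted p = 0.0029). Of the 20 Notch pathway genes, 1 rose, 11 fell and 8 did not pass (1 and 12 adjusted over the list alone). Notch pathway genes had a downward camera adjusted p = 0.000296, and adjusted p = 0.485 with an estimated correlation. The T-box gene bifid (bi, also optomotor-blind), a Dpp target, fell by 1.05 (adjusted p = 9.9e-05) and dachshund (dac) by 1.46 (adjusted p = 0.0045). Of the 37 morphogen and patterning genes, 2 rose, 11 fell and 24 did not pass (4 and 13 adjusted over the list alone). The list had a downward camera adjusted p = 0.0285, and 0.691 with an estimated correlation. Of the 10 Wg pathway targets, 1 rose, 4 fell and 5 did not pass (1 and 4 adjusted over the list alone, camera adjusted p = 0.14). Of the 5 Hox genes, 0 rose, 2 fell and 3 did not pass (0 and 2 adjusted over the list alone, camera adjusted p = 0.384). Of the 19 polarity and junction genes, 7 rose, 0 fell and 12 did not pass (7 and 0 adjusted over the list alone). The list had an upward camera adjusted p = 0.0107, and 0.537 with an estimated correlation.

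Of the genes induced by the steroid ecdysone, ImpE2 fell by 5.03 ± 0.99 (adjusted p = 0.0029), from 1779 ± 1173 to 54.6 ± 28.1 CPM, and the nuclear receptor gene Eip78C by 5.74 (adjusted p = 0.0036). Of the 21 ecdysone response genes, 1 rose, 8 fell and 12 did not pass (3 and 12 adjusted over the list alone). The list had a downward camera adjusted p = 0.0169, and 0.612 with an estimated correlation. Within the control group ImpE2 was lowest in replicate 2, at 2206, 452 and 2678 CPM in replicates 1, 2 and 3. Of the heat shock genes, Hsp27 fell by 1.78 (adjusted p = 0.0018) and Hsp67Ba by 1.88 (0.0035). Handling was not tested as a cause. Of the 15 heat shock genes, 0 rose, 3 fell and 12 did not pass (0 and 13 adjusted over the list alone). Heat shock genes had a downward camera adjusted p = 0.00494, and adjusted p = 0.643 with an estimated correlation. All 7 salivary gland genes fell (0 and 7 adjusted over the list alone, downward camera adjusted p = 0.000187, and adjusted p = 0.485 with an estimated correlation), Sgs3 from 888 ± 1453 to 0.134 ± 0.13 CPM. Of the 13 differentiated muscle genes, 0 rose, 2 fell and 11 did not pass (0 and 9 adjusted over the list alone). The list had a downward camera adjusted p = 0.00715, and 0.637 with an estimated correlation. Of the 7 markers of adult muscle progenitors, 0 rose, 3 fell and 4 did not pass (0 and 3 adjusted over the list alone). The list had a downward camera adjusted p = 0.0426, and 0.485 with an estimated correlation. Amalgam (Ama) was at -1.01 ± 0.17. Of the 9 fat body genes, 0 rose, 1 fell and 8 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.0788). Of the 13 hemocyte genes, 0 rose, 0 fell and 13 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.166). The roX RNAs were at 0.66 ± 0.42 for roX1 and 1.16 ± 0.43 for roX2, without a call (1 rise and 0 falls of 2 adjusted over the list alone).

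The glycolytic enzyme gene Tpi fell by 0.57 (adjusted p = 0.0094), a call that was lost without wts replicate 3 (-0.52, adjusted p = 0.051). Of the 17 glycolysis and hypoxia genes, 1 rose, 6 fell and 10 did not pass (1 and 7 adjusted over the list alone). The list had a downward camera adjusted p = 0.0119, and 0.5 with an estimated correlation. The largest rises included the ion channel gene ppk13 (2L, from 21086790), from 0.0783 ± 0.0221 to 55.1 ± 1.93 CPM, and the noncoding gene CR45923 (2R, from 4621118; 4.39 ± 0.24, adjusted p = 1.8e-08). In cic wts discs ppk13 measured 0.125 ± 0.0645 CPM at day 5 and 0.115 ± 0.074 at day 9, against 35.0 ± 4.51 in wts discs at day 9, and its interaction of cic with wts at day 5 was -9.76 ± 0.63 (adjusted p = 3.1e-07). In all, 900 genes rose and 735 fell. With total-count scaling the split was 635 up and 1081 down, or 37% up against 55%. The count of 1635 was 813 without wts replicate 3, 1058 without control replicate 1 and 1075 without wts replicate 1.

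**Figure D2:**
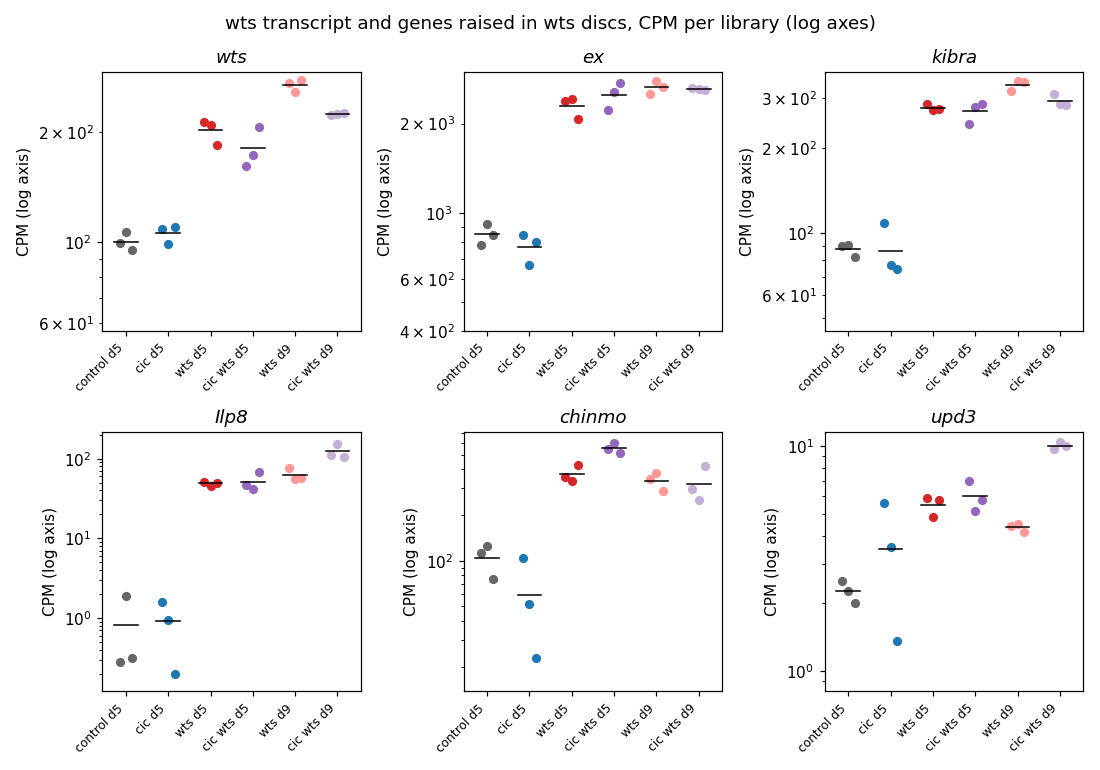
CPM on log axes for wts, ex, kibra, Ilp8, chinmo and upd3 in each of the 18 libraries (points), with the mean of each group of 3 (lines). All 12 libraries of wts and cic wts discs lie above all 6 control and cic libraries for wts, ex, kibra, Ilp8 and chinmo; Ilp8 averaged 0.821 CPM in control and 49.0 in wts discs at day 5.

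Loss of both genes, in cic wts against control discs at day 5, was compared to find the genes that change when both pathways are altered. The aos transcript rose by 2.39 ± 0.11 (adjusted p = 8.8e-09), from 29.6 ± 2.51 to 155 ± 9.47 CPM, sty by 1.45 ± 0.14 (adjusted p = 4.2e-06), pnt by 0.98 ± 0.11 (adjusted p = 1.2e-05) and Mkp3 by 0.64 ± 0.12 (adjusted p = 0.0015). Other members of the list fell: rho by 2.08 (adjusted p = 0.00056), the EGFR ligand gene vein (vn) by 0.52 (adjusted p = 4.2e-05) and mirror (mirr), a gene that specifies the notum, by 0.93 (adjusted p = 0.00049). Of the 15 Ras/EGFR and Cic target genes, 5 rose, 5 fell and 5 did not pass (5 and 6 adjusted over the list alone, upward camera adjusted p = 0.78, with a median of -0.17 and a mean of -0.16, not all of 1 sign). Of the Yorkie targets, Ilp8 was at 5.92 ± 0.49, ex at 1.56 ± 0.10 and kibra at 1.62 ± 0.11 (adjusted p = 1.8e-07), while vg fell by 0.83. Of the 20 Yki/Sd target genes, 9 rose, 3 fell and 8 did not pass (9 and 4 adjusted over the list alone). Yki/Sd target genes had an upward camera adjusted p = 0.0328, and adjusted p = 0.57 with an estimated correlation. The chinmo transcript rose by 2.40 ± 0.37 (adjusted p = 0.00032), os by 1.31 ± 0.12 (adjusted p = 2.1e-06) and upd3 by 1.39 ± 0.32 (adjusted p = 0.0061). Of the 11 JAK/STAT ligands and targets, 6 rose, 0 fell and 5 did not pass (7 and 0 adjusted over the list alone). JAK/STAT ligands and targets had an upward camera adjusted p = 0.00254, and adjusted p = 0.463 with an estimated correlation. The cic transcript was at -0.34 ± 0.12 (adjusted p = 0.047), a call lost in 5 of 6 fits that lacked 1 library (adjusted p from 0.073 to 0.18).

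Of the Notch target genes, E(spl)m2-BFM fell by 2.54 (adjusted p = 7.2e-07), E(spl)malpha-BFM by 2.48 and E(spl)mdelta-HLH by 2.04. Of the 20 Notch pathway genes, 0 rose, 13 fell and 7 did not pass (0 and 14 adjusted over the list alone). Notch pathway genes had a downward camera adjusted p = 2.39e-08, and adjusted p = 0.391 with an estimated correlation. The bi transcript fell by 1.70 (adjusted p = 7e-07), whereas brinker (brk), the repressor that Dpp signalling shuts off, rose by 1.38 ± 0.15 (adjusted p = 1.3e-05). Of the 37 morphogen and patterning genes, 3 rose, 21 fell and 13 did not pass (6 and 23 adjusted over the list alone). Morphogen and patterning genes had a downward camera adjusted p = 7.73e-07, and adjusted p = 0.485 with an estimated correlation. Optix fell by 2.01 (adjusted p = 3.3e-06) and dac by 1.71. Of the 12 retinal determination genes, 0 rose, 5 fell and 7 did not pass (0 and 5 adjusted over the list alone). Retinal determination genes had a downward camera adjusted p = 0.00393, and adjusted p = 0.5 with an estimated correlation. Of the genes of DNA replication and division, double parked (dup; 0.36 ± 0.08) and pavarotti (pav; 0.32 ± 0.06) rose, as did the cyclin-dependent kinase inhibitor dacapo (dap; 0.56 ± 0.14). Of the 33 cell cycle genes, 12 rose, 1 fell and 20 did not pass (13 and 1 adjusted over the list alone). Cell cycle genes had an upward camera adjusted p = 0.00481, and adjusted p = 0.506 with an estimated correlation. The cell death genes hid and Dronc were at -0.90 ± 0.19 and -0.58 ± 0.12. Of the 13 apoptosis genes, 1 rose, 5 fell and 7 did not pass (2 and 5 adjusted over the list alone, camera adjusted p = 0.185). Of the 8 peripodial and squamous epithelium genes, 1 rose, 4 fell and 3 did not pass (1 and 4 adjusted over the list alone). The list had a downward camera adjusted p = 0.0302, and 0.485 with an estimated correlation.

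Of the ecdysone response genes, ImpE2 fell by 6.85 (adjusted p = 0.00039) and ImpE3 by 5.76 (adjusted p = 0.00034). Of the 21 ecdysone response genes, 1 rose, 13 fell and 7 did not pass (1 and 14 adjusted over the list alone). Ecdysone response genes had a downward camera adjusted p = 0.000587, and adjusted p = 0.485 with an estimated correlation. Blimp-1, an ecdysone-induced repressor outside that list, fell by 7.71 (adjusted p = 0.007). Pfk fell by 0.84 (adjusted p = 1.9e-05) and Tpi by 0.92. Of the 17 glycolysis and hypoxia genes, 0 rose, 7 fell and 10 did not pass (0 and 7 adjusted over the list alone). Glycolysis and hypoxia genes had a downward camera adjusted p = 0.00856, and adjusted p = 0.485 with an estimated correlation. The claudin gene sinuous (sinu) rose by 0.67 ± 0.09 (adjusted p = 7.9e-05). All 7 salivary gland genes fell (0 and 7 adjusted over the list alone, downward camera adjusted p = 0.00303, and adjusted p = 0.579 with an estimated correlation). Of the 15 heat shock genes, 0 rose, 3 fell and 12 did not pass (0 and 3 adjusted over the list alone, camera adjusted p = 0.0633). Of the 13 differentiated muscle genes, 0 rose, 8 fell and 5 did not pass (1 and 11 adjusted over the list alone). Differentiated muscle genes had a downward camera adjusted p = 0.00109, and adjusted p = 0.619 with an estimated correlation. Of the 13 hemocyte genes, 1 rose, 1 fell and 11 did not pass (0 and 1 adjusted over the list alone, camera adjusted p = 0.861). Hml was at 2.66 ± 0.91 (adjusted p = 0.048), a call lost in 4 of 6 fits that lacked 1 library, and at -0.35 (adjusted p = 0.64) without cic wts replicate 1. Of the 7 markers of adult muscle progenitors, 0 rose, 5 fell and 2 did not pass (0 and 5 adjusted over the list alone). Markers of adult muscle progenitors had a downward camera adjusted p = 0.000211, and adjusted p = 0.295 with an estimated correlation. Ama was at -1.83 ± 0.18. The roX RNAs were at 0.87 ± 0.42 for roX1 and 1.21 ± 0.43 for roX2, without a call (1 rise and 0 falls of 2 adjusted over the list alone). In all, 1014 genes rose and 1008 fell. When only the 6 libraries compared entered the fit, the count of 2022 was 1044, and that of 1635 in wts discs was 1283. With total-count scaling the split was 749 up and 1293 down, or 36.7% up against 50.1%.

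**Figure D3:**
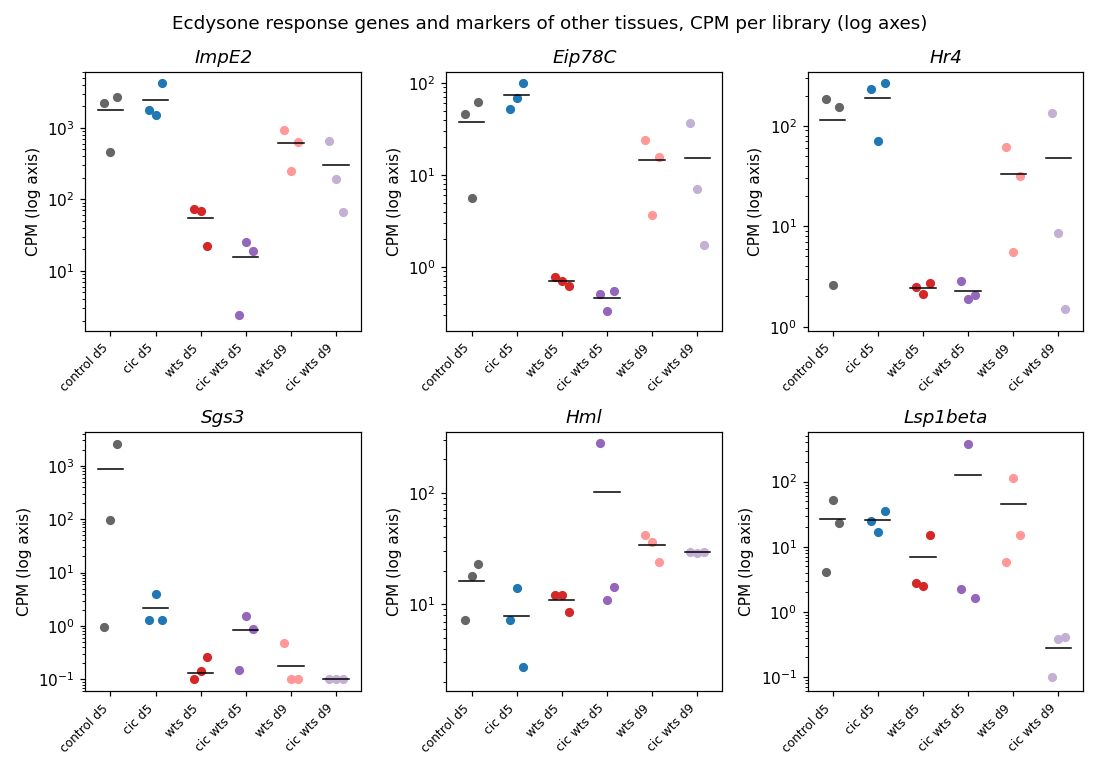
CPM on log axes for the ecdysone response genes ImpE2, Eip78C and Hr4 and for Sgs3 (salivary gland), Hml (hemocytes) and Lsp1beta (fat body) in each of the 18 libraries (points), with the mean of each group of 3 (lines); values under 0.1 CPM are drawn at 0.1. The ImpE2 transcript averaged 1779 CPM in control and 54.6 in wts discs at day 5, and Sgs3 ranged from 0.978 to 2564 CPM among the control libraries.

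Loss of cic in wts mutant discs, cic wts against wts at day 5, was compared to find the genes that respond to cic when Hippo signalling is lost. The aos transcript rose by 2.00 ± 0.11 (adjusted p = 3.4e-08), from 38.8 ± 1.88 to 155 ± 9.47 CPM, pnt by 1.79 ± 0.11 (adjusted p = 7.4e-08) and sty by 1.16 ± 0.14 (adjusted p = 0.00016), while vn fell by 0.74 (adjusted p = 4.5e-06). Of the 15 Ras/EGFR and Cic target genes, 4 rose, 1 fell and 10 did not pass (4 and 3 adjusted over the list alone, upward camera adjusted p = 0.203, with a median of -0.04 and a mean of 0.03, not all of 1 sign). The transcription factor gene Stat92E of the JAK/STAT pathway rose by 0.32 ± 0.06 (adjusted p = 0.0055). Of the 11 JAK/STAT ligands and targets, 2 rose, 0 fell and 9 did not pass (3 and 0 adjusted over the list alone). JAK/STAT ligands and targets had an upward camera adjusted p = 0.00639, and adjusted p = 0.485 with an estimated correlation. Of the patterning genes, the T-box gene Doc2 fell by 1.19 (adjusted p = 0.00077), the notum gene eyegone (eyg) by 0.86 (adjusted p = 6.9e-05) and the morphogen gene dpp by 0.58 (adjusted p = 0.00046). Of the 37 morphogen and patterning genes, 0 rose, 10 fell and 27 did not pass (1 and 16 adjusted over the list alone). Morphogen and patterning genes had a downward camera adjusted p = 3.37e-07, and adjusted p = 0.481 with an estimated correlation. Optix fell by 1.37 (adjusted p = 0.00055). Of the 12 retinal determination genes, 0 rose, 3 fell and 9 did not pass (0 and 6 adjusted over the list alone). Retinal determination genes had a downward camera adjusted p = 9.6e-05, and adjusted p = 0.481 with an estimated correlation. E(spl)m2-BFM fell by 1.35 and E(spl)m6-BFM by 1.49 (adjusted p = 0.0072). Of the 20 Notch pathway genes, 0 rose, 5 fell and 15 did not pass (0 and 10 adjusted over the list alone). Notch pathway genes had a downward camera adjusted p = 7.73e-07, and adjusted p = 0.443 with an estimated correlation. The peptidase gene Ance fell by 1.48 (adjusted p = 4e-04), from 319 ± 59.1 to 115 ± 30.4 CPM. Of the 8 peripodial and squamous epithelium genes, 0 rose, 3 fell and 5 did not pass (0 and 4 adjusted over the list alone). Peripodial and squamous epithelium genes had a downward camera adjusted p = 0.00333, and adjusted p = 0.391 with an estimated correlation.

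Pfk fell by 0.75 (adjusted p = 0.00027) and the cuticle gene Cpr64Aa by 3.15 (adjusted p = 8e-06). The twist gene (twi), a marker of adult muscle progenitors, fell by 0.92 (adjusted p = 0.0032). Of the 7 such markers, 0 rose, 3 fell and 4 did not pass (0 and 4 adjusted over the list alone). Such markers had a downward camera adjusted p = 0.000162, and adjusted p = 0.295 with an estimated correlation. Of the 19 ribosome biogenesis genes, 0 rose, 0 fell and 19 did not pass (1 and 0 adjusted over the list alone). Ribosome biogenesis genes had an upward camera adjusted p = 0.000678, and adjusted p = 0.5 with an estimated correlation. Of the 13 hemocyte genes, 0 rose, 0 fell and 13 did not pass (8 and 0 adjusted over the list alone). Hemocyte genes had an upward camera adjusted p = 0.0226, and adjusted p = 0.637 with an estimated correlation. Hml was high in cic wts replicate 1, without which the direction of the list turned and its call was lost. Of the 9 fat body genes, 0 rose, 0 fell and 9 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.187). Lsp1beta was high in cic wts replicate 2. Several genes far from the control level in wts discs were nearer to it, or beyond it, in cic wts discs. The potassium channel gene SK (X, from 5340236) measured 7.62 ± 2.62 CPM in control, 0.266 ± 0.199 in wts and 30.4 ± 7.80 in cic wts discs, CG4562 (3R, from 19865417) 15.9 ± 2.15, 1.48 ± 0.181 and 16.1 ± 1.81 CPM, and CG7054 (3R, from 22464985) 17.8 ± 1.82, 1.95 ± 0.815 and 23.8 ± 0.468 CPM. CR45923 measured 2.48 ± 0.343, 52.2 ± 5.34 and 2.54 ± 0.943 CPM. In all, 94 genes rose and 168 fell, 262 in total. The count was 105 without wts replicate 1, 162 without wts replicate 2 and 172 without cic wts replicate 1, and 478 with DESeq2. The JNK and apoptosis gene hid fell by 1.01 and lost its call without wts replicate 1 (-0.93, adjusted p = 0.056).

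Whether the effect of cic differed between both backgrounds was tested as the interaction at day 5, the log2 effect of cic in wts discs minus that in the control background. The effect on pnt was larger in wts discs by 1.33 ± 0.15 (adjusted p = 0.00014), on aos by 1.1 ± 0.16 (adjusted p = 0.0016) and on sty by 0.92 ± 0.19 (adjusted p = 0.021). The sty call was lost without control replicate 2 (adjusted p = 0.055), cic replicate 2 (adjusted p = 0.062), wts replicate 1 (adjusted p = 0.051) or wts replicate 2 (adjusted p = 0.056). The interaction was negative for vn, at -0.52 ± 0.09 (adjusted p = 0.0078), and for Ance it was -1.41 ± 0.27 (adjusted p = 0.014): Ance measured 425 ± 24.0 CPM in control and 407 ± 59.4 CPM in cic discs, against 319 ± 59.1 and 115 ± 30.4 CPM in wts and cic wts discs. Doc2 had an interaction of -1.38 ± 0.24 (adjusted p = 0.0076), eyg of -0.75 ± 0.13 (adjusted p = 0.0078), E(spl)m6-BFM of -2.26 ± 0.38 (adjusted p = 0.0071) and hid of -1.44 ± 0.27 (adjusted p = 0.013). Of the 15 Ras/EGFR and Cic target genes, 3 had a positive and 1 a negative interaction and 11 did not pass (3 and 1 adjusted over the list alone, upward camera adjusted p = 0.791, with a median of -0.09 and a mean of -0.14, not all of 1 sign). Of the 37 morphogen and patterning genes, 0 had a positive and 6 a negative interaction and 31 did not pass (0 and 10 adjusted over the list alone). The list had a downward camera adjusted p = 2.2e-05, and 0.485 with an estimated correlation. Of the 20 Notch pathway genes, 0 had a positive and 2 a negative interaction and 18 did not pass (0 and 5 adjusted over the list alone). Notch pathway genes had a downward camera adjusted p = 4e-04, and adjusted p = 0.485 with an estimated correlation. Of the 33 cell cycle genes, 2 had a positive and 0 a negative interaction and 31 did not pass (10 and 0 adjusted over the list alone). Cell cycle genes had an upward camera adjusted p = 7.13e-05, and adjusted p = 0.481 with an estimated correlation. Of the 13 apoptosis genes, 0 had a positive and 2 a negative interaction and 11 did not pass (0 and 3 adjusted over the list alone). Apoptosis genes had a downward camera adjusted p = 0.0169, and adjusted p = 0.391 with an estimated correlation. Of the 13 Minute and Xrp1 response genes, 0 had a positive and 1 a negative interaction and 12 did not pass (0 and 3 adjusted over the list alone). The list had a downward camera adjusted p = 0.0209, and 0.485 with an estimated correlation. Of the 20 Yki/Sd target genes, 0 had a positive and 1 a negative interaction and 19 did not pass (0 and 3 adjusted over the list alone). Yki/Sd target genes had a downward camera adjusted p = 0.0494, and adjusted p = 0.612 with an estimated correlation.

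The interaction passed for 175 genes, 67 positive and 108 negative. For 108 of them the effect of cic was larger in the wts background, and for 67 in the control background. Of the latter, 54 were called in cic against control, among them Dscam4 (interaction 5.68 ± 0.21), CR43144 (-3.80 ± 0.27) and Snap25 (-3.35 ± 0.39). Cpr64Aa had an interaction of -1.97 ± 0.38, SK of 6.72 ± 0.58, CG7054 of 3.99 ± 0.48, CG4562 of 4.40 ± 0.34 and CR45923 of -4.24 ± 0.34. Across all 9004 genes, the effects of cic in both backgrounds, which share no library, had a Pearson r of -0.019 and a Spearman rho of -0.022; genes are not independent replicates, so no p-value is given. Leaving out 1 library at a time gave an r from -0.211 (without wts day 5 replicate 2) to 0.057 (without cic wts day 5 replicate 2), with a jackknife SE of 0.224, and counts simulated with no effect gave -0.0367. Of the genes called, 6 rose in both backgrounds (0.9 from independent lists), 2 fell in both (1.14), 2 rose in the control background and fell in wts discs (1.6), and 2 did the reverse (0.64). Lists of markers of other tissues were tested too: of the 13 hemocyte genes, 0 had a positive and 0 a negative interaction and 13 did not pass (7 and 1 adjusted over the list alone, upward camera adjusted p = 0.0227, and adjusted p = 0.637 with an estimated correlation), and of the 7 salivary gland genes, 0 had a positive and 0 a negative interaction and 7 did not pass (1 and 0 adjusted over the list alone, upward camera adjusted p = 0.000292, and adjusted p = 0.485 with an estimated correlation). Of the 7 markers of adult muscle progenitors, 0 had a positive and 3 a negative interaction and 4 did not pass (0 and 3 adjusted over the list alone). Markers of adult muscle progenitors had a downward camera adjusted p = 0.00425, and adjusted p = 0.391 with an estimated correlation. The interaction count was 92 without wts replicate 1, 102 without control replicate 2, 102 without cic replicate 2, 391 with DESeq2 and 78 when only the 12 day 5 libraries entered the fit.

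**Figure D4:**
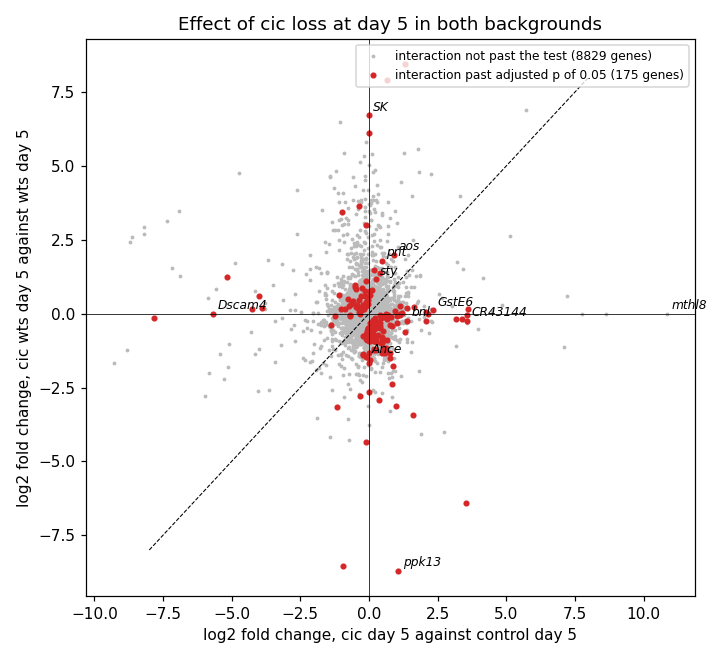
Log2 fold change of each of the 9004 tested genes after loss of cic at day 5, in the control background (horizontal axis) and in wts discs (vertical axis); red points are the 175 genes whose interaction passed and the dashed line marks equal effects. The aos, pnt and sty points lie above the dashed line, and Dscam4 and CR43144 lie near the horizontal axis.

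At day 9, loss of cic in wts discs raised aos by 2.07 ± 0.11 (adjusted p = 2e-08), pnt by 1.76 ± 0.11 (adjusted p = 6e-08), sty by 1.15 ± 0.14 (adjusted p = 9.6e-05) and Mkp3 by 0.72 ± 0.12 (adjusted p = 0.0018), and lowered vn by 1.28 (adjusted p = 9.1e-09). Of the 15 Ras/EGFR and Cic target genes, 4 rose, 1 fell and 10 did not pass (5 and 2 adjusted over the list alone, upward camera adjusted p = 0.113, with a median of -0.01 and a mean of 0.24, not all of 1 sign). The FGF ligand gene bnl rose by 1.84 ± 0.26 (adjusted p = 0.00044), the FGF8-like gene pyramus (pyr) by 1.38 ± 0.12 (adjusted p = 3.1e-06), the insulin-binding protein gene ImpL2 by 2.00 ± 0.36 (adjusted p = 0.003) and os by 0.74 ± 0.11 (adjusted p = 0.00093). Of the 22 secreted growth signal genes, 5 rose, 4 fell and 13 did not pass (8 and 4 adjusted over the list alone, camera adjusted p = 0.216). Of the 11 JAK/STAT ligands and targets, 4 rose, 0 fell and 7 did not pass (5 and 0 adjusted over the list alone). JAK/STAT ligands and targets had an upward camera adjusted p = 0.00254, and adjusted p = 0.463 with an estimated correlation. The lactate dehydrogenase gene ImpL3 rose by 3.25 ± 0.60 (adjusted p = 0.0033). Of the 17 glycolysis and hypoxia genes, 3 rose, 0 fell and 14 did not pass (3 and 0 adjusted over the list alone, camera adjusted p = 0.25). The replication genes Orc1 and Mcm2 were at 0.46 ± 0.08 and 0.39 ± 0.07. Of the 33 cell cycle genes, 8 rose, 0 fell and 25 did not pass (19 and 1 adjusted over the list alone). Cell cycle genes had an upward camera adjusted p = 7.73e-07, and adjusted p = 0.391 with an estimated correlation.

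In cic wts discs at day 9, Daughters against dpp (Dad), a Dpp target, fell by 1.27 (adjusted p = 1.1e-06), vg by 0.86 (adjusted p = 5e-06), tailup (tup) by 1.29 (adjusted p = 0.00097), Doc3 by 1.34 and eyg by 0.51. Of the 37 morphogen and patterning genes, 6 rose, 14 fell and 17 did not pass (7 and 16 adjusted over the list alone). Morphogen and patterning genes had a downward camera adjusted p = 0.00534, and adjusted p = 0.633 with an estimated correlation. Optix fell by 1.85 (adjusted p = 1.7e-05) and sine oculis (so) by 0.74. Of the 12 retinal determination genes, 0 rose, 3 fell and 9 did not pass (0 and 4 adjusted over the list alone). Retinal determination genes had a downward camera adjusted p = 0.0204, and adjusted p = 0.619 with an estimated correlation. Ance fell by 1.39 (adjusted p = 0.00044). Of the 8 peripodial and squamous epithelium genes, 1 rose, 4 fell and 3 did not pass (1 and 6 adjusted over the list alone). Peripodial and squamous epithelium genes had a downward camera adjusted p = 0.000408, and adjusted p = 0.295 with an estimated correlation. The tracheal genes breathless (btl), the FGF receptor, and trachealess (trh) were lower: btl fell by 1.09 (adjusted p = 0.00033) and trh fell by 0.65 (adjusted p = 8.6e-05). Of the 9 tracheal genes, 0 rose, 4 fell and 5 did not pass (0 and 4 adjusted over the list alone). Tracheal genes had a downward camera adjusted p = 0.00658, and adjusted p = 0.391 with an estimated correlation. Of the 7 markers of adult muscle progenitors, 0 rose, 2 fell and 5 did not pass (0 and 6 adjusted over the list alone). Markers of adult muscle progenitors had a downward camera adjusted p = 0.000292, and adjusted p = 0.295 with an estimated correlation. Of the 15 basement membrane genes, 0 rose, 3 fell and 12 did not pass (1 and 3 adjusted over the list alone). Basement membrane genes had a downward camera adjusted p = 0.0147, and adjusted p = 0.537 with an estimated correlation. Cpr64Aa fell by 4.30 (adjusted p = 4.2e-07). Of the 16 cuticle genes, 0 rose, 4 fell and 12 did not pass (1 and 5 adjusted over the list alone). Cuticle genes had a downward camera adjusted p = 0.000743, and adjusted p = 0.443 with an estimated correlation. Of the 21 ecdysone response genes, 0 rose, 2 fell and 19 did not pass (0 and 4 adjusted over the list alone). Ecdysone response genes had a downward camera adjusted p = 0.00237, and adjusted p = 0.488 with an estimated correlation. Of the 9 fat body genes, 0 rose, 0 fell and 9 did not pass (0 and 2 adjusted over the list alone). Fat body genes had a downward camera adjusted p = 0.0341, and adjusted p = 0.637 with an estimated correlation.

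At day 9, cic wts against wts, 260 genes rose and 361 fell, 621 in total. The count was 307 without cic wts day 9 replicate 2, 324 without wts day 9 replicate 1, 392 without cic wts day 9 replicate 1 and 412 without cic wts day 9 replicate 3. Between the days, the effect of cic in wts discs, measured on separate libraries, had a Pearson r of 0.268 and a Spearman rho of 0.383 across the 9004 genes. Of the genes called, 63 rose on both days (2.71 from independent lists), 124 fell on both (6.74) and 0 were called by edgeR in opposite directions (3.77 and 4.85 from independent lists). The interaction of day and cic passed for 0 genes with edgeR, 593 had an unadjusted p under 0.05, and DESeq2 called 32. Camera called lists for this interaction: upward for cell cycle (adjusted p = 0.000657), Notch pathway (0.000902), glycolysis and hypoxia (0.0169), secreted growth signal (0.0285) and germline genes (0.0494). It was downward for fat body (4e-04), heat shock (0.00856), cuticle (0.00985), Hox (0.0173), ribosome biogenesis (0.02) and hemocyte genes (0.0236). With an estimated correlation their adjusted p ranged from 0.463 to 0.673. None of their genes passed over all genes tested. Adjusted over the list alone, 5 fat body and 4 hemocyte genes had a negative interaction, 1 glycolysis gene a positive one, 2 secreted growth signal genes a positive and 1 a negative one, and the other lists had 0. Without cic wts day 5 replicate 1 the hemocyte direction turned.

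The change with larval age was measured in wts discs as day 9 against day 5. The PDGF/VEGF-like ligand gene Pvf1 rose by 0.93 ± 0.17 (adjusted p = 0.0071), the translation elongation factor gene Ef1alpha100E by 3.66 ± 0.56 (adjusted p = 0.002), from 8.45 ± 3.56 to 108 ± 5.81 CPM, and Timp by 0.98 ± 0.16 (adjusted p = 0.0031). The vg transcript fell by 0.43 (adjusted p = 0.0061). The ecdysone response gene ImpE2 was at 3.48 ± 0.92 (adjusted p = 0.036), ImpE3 at 3.49 ± 0.79 (adjusted p = 0.019) and Eip78C at 4.36 ± 1.17 (adjusted p = 0.037). Of the 21 ecdysone response genes, 10 rose, 0 fell and 11 did not pass (13 and 0 adjusted over the list alone). Ecdysone response genes had an upward camera adjusted p = 1.37e-05, and adjusted p = 0.459 with an estimated correlation. In fits that lacked 1 library, ImpE2 (adjusted p from 0.07 to 0.14) and Eip78C (0.082 to 0.13) lost their calls in 5 of 6 and ImpE3 (0.052 to 0.098) in 3. Of the 22 secreted growth signal genes, 4 rose, 0 fell and 18 did not pass (5 and 0 adjusted over the list alone). Secreted growth signal genes had an upward camera adjusted p = 0.0156, and adjusted p = 0.459 with an estimated correlation. Of the 33 cell cycle genes, 0 rose, 3 fell and 30 did not pass (0 and 10 adjusted over the list alone). Cell cycle genes had a downward camera adjusted p = 0.00108, and adjusted p = 0.485 with an estimated correlation. Of the 15 basement membrane genes, 2 rose, 0 fell and 13 did not pass (7 and 0 adjusted over the list alone). Basement membrane genes had an upward camera adjusted p = 0.00495, and adjusted p = 0.485 with an estimated correlation. Of the 19 ribosome biogenesis genes, 0 rose, 2 fell and 17 did not pass (0 and 2 adjusted over the list alone). Ribosome biogenesis genes had a downward camera adjusted p = 0.017, and adjusted p = 0.637 with an estimated correlation. Of the 16 cuticle genes, 4 rose, 0 fell and 12 did not pass (6 and 2 adjusted over the list alone). Cuticle genes had an upward camera adjusted p = 0.0244, and adjusted p = 0.485 with an estimated correlation.

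With age in wts discs, of the 13 differentiated muscle genes, 0 rose, 1 fell and 12 did not pass (0 and 8 adjusted over the list alone). Differentiated muscle genes had a downward camera adjusted p = 0.00264, and adjusted p = 0.637 with an estimated correlation. Of the 13 hemocyte genes, 0 rose, 0 fell and 13 did not pass (3 and 0 adjusted over the list alone). Hemocyte genes had an upward camera adjusted p = 0.0128, and adjusted p = 0.633 with an estimated correlation. Of the 7 markers of adult muscle progenitors, 2 rose, 0 fell and 5 did not pass (3 and 0 adjusted over the list alone). Markers of adult muscle progenitors had an upward camera adjusted p = 0.0285, and adjusted p = 0.485 with an estimated correlation. In all, 377 genes rose and 243 fell, 620 in total. The count was 118 without wts day 5 replicate 3, 188 without wts day 5 replicate 2, 224 without wts day 9 replicate 3, 290 without wts day 9 replicate 2 and 313 without wts day 9 replicate 1. It was 1075 with DESeq2, 1031 when only the 6 libraries compared entered the fit and 1159 with the roX level as a covariate.

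In cic wts discs, bnl rose between day 5 and day 9 by 2.57 ± 0.27 (adjusted p = 1e-04), from 7.63 ± 1.81 to 45.3 ± 12.4 CPM. ImpL2 rose by 1.89 ± 0.36 (adjusted p = 0.005), Pvf1 by 1.35 ± 0.17 (adjusted p = 0.00047) and ImpL3 by 3.82 ± 0.62 (adjusted p = 0.0019). Of the 22 secreted growth signal genes, 10 rose, 1 fell and 11 did not pass (15 and 3 adjusted over the list alone). Secreted growth signal genes had an upward camera adjusted p = 0.000211, and adjusted p = 0.295 with an estimated correlation. The eye gene eyes absent (eya) rose by 1.22 ± 0.21 (adjusted p = 0.0026), eyg by 0.81 ± 0.09 (adjusted p = 0.00022) and its relative toe by 1.02 ± 0.16 (adjusted p = 0.0017), while vg fell by 0.91 (adjusted p = 2.3e-05), bi by 0.96 and vn by 0.38. Of the 37 morphogen and patterning genes, 10 rose, 4 fell and 23 did not pass (17 and 5 adjusted over the list alone). Morphogen and patterning genes had an upward camera adjusted p = 0.00307, and adjusted p = 0.619 with an estimated correlation. The cell death gene hid rose by 1.07 ± 0.19 (adjusted p = 0.0037) and Diap1 by 0.32 ± 0.06 (adjusted p = 0.0061). Of the 13 apoptosis genes, 4 rose, 1 fell and 8 did not pass (6 and 1 adjusted over the list alone). Apoptosis genes had an upward camera adjusted p = 0.0233, and adjusted p = 0.391 with an estimated correlation. The RNA polymerase I gene RpI1 fell by 0.52 (adjusted p = 0.0076), a call lost without cic wts day 9 replicate 1 (-0.47, adjusted p = 0.055). Of the 19 ribosome biogenesis genes, 1 rose, 11 fell and 7 did not pass (2 and 13 adjusted over the list alone). Ribosome biogenesis genes had a downward camera adjusted p = 9.6e-05, and adjusted p = 0.485 with an estimated correlation. The Notch-responsive repressor gene deadpan (dpn) fell by 1.67 (adjusted p = 0.00065). Of the 20 Notch pathway genes, 3 rose, 1 fell and 16 did not pass (3 and 1 adjusted over the list alone). Notch pathway genes had an upward camera adjusted p = 0.0494, and adjusted p = 0.637 with an estimated correlation.

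The ecdysone-induced gene ImpE1 rose by 2.82 ± 0.60 (adjusted p = 0.0097) in cic wts discs with age, a call lost without cic wts day 9 replicate 1 (2.29, adjusted p = 0.061). Of the 21 ecdysone response genes, 7 rose, 1 fell and 13 did not pass (12 and 3 adjusted over the list alone). The list had an upward camera adjusted p = 0.00121, and 0.485 with an estimated correlation. Ama, a marker of adult muscle progenitors, rose by 1.16 ± 0.17 (adjusted p = 0.0014). Of the 7 such markers, 2 rose, 0 fell and 5 did not pass (2 and 0 adjusted over the list alone). Such markers had an upward camera adjusted p = 0.0494, and 0.485 with an estimated correlation. Of the 9 fat body genes, 0 rose, 3 fell and 6 did not pass (0 and 5 adjusted over the list alone, camera adjusted p = 0.0988). Lsp1beta was at 2.24, 382 and 1.61 CPM in day 5 replicates 1, 2 and 3. Of the 13 hemocyte genes, 1 rose, 1 fell and 11 did not pass (1 and 2 adjusted over the list alone, upward camera adjusted p = 0.714, with a median of -0.48 and a mean of -1.05, not all of 1 sign). PPO1 was at 509.6, 7.04 and 15.3 CPM in the same replicates. Of the 13 differentiated muscle genes, 0 rose, 3 fell and 10 did not pass (0 and 10 adjusted over the list alone). The list had a downward camera adjusted p = 0.00148, and 0.619 with an estimated correlation. In all, 546 genes rose and 409 fell, 955 in total. The count was 237 without cic wts day 9 replicate 1, 364 without cic wts day 5 replicate 1 and 402 without cic wts day 9 replicate 2.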

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

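Tests of salivary gland RNA, larval stage, mutant cell share, scaling and the third chromosome of another strain, and the roX covariate, were chosen only after the results they measure were seen. The interaction passed for 175 genes, which stock differences may partly explain. Interactions (log2) were positive for aos (1.1), pnt (1.33), sty (0.92), pyr (0.72), Stat92E (0.35), dup (0.53), CycB3 (0.31), Dscam4 (5.68), SK (6.72), CG4562 (4.4) and CG7054 (3.99). They were negative for vn (-0.52), bnl (-1.61), dpp (-0.5), Ance (-1.41), Doc2 (-1.38), eyg (-0.75), ara (-0.73), hid (-1.44), Dronc (-0.81), E(spl)m6-BFM (-2.26), E(spl)m2-BFM (-1.12), GstE6 (-2.21), Him (-2.11), Ama (-1.04), twi (-0.96), CR43144 (-3.8), Snap25 (-3.35), CR45923 (-4.24), Cpr64Aa (-1.97), ppk13 (-9.76), CG4362 (-3.47) and Pfk (-0.59). Leaving out 1 of the 12 day 5 libraries ended the call of CycB3 and CG4362 in 10 fits, of Stat92E, ara and Ama in 9, of pyr, bnl, GstE6 and Pfk in 8, of dpp, E(spl)m2-BFM and twi in 7, of sty and dup in 4, of Him in 3 and of Dronc in 1 (adjusted p from 0.051 to 0.14); the others named kept it in every such fit. Of 100 assignments of the 12 day 5 libraries, the real one included, 3 gave at least 175 genes. Another, with cic labels swapped in 1 background (211), tests the summed cic effect, and 1 gave 546. So chance or further structure is not excluded.

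The larger effect of cic on aos, pnt and sty in wts discs was weighed against scaling and the share of mutant cells. Scaling is argued against, since the lowest ratio of the 3 interactions under other scalings to the reported value was 1.01 and all 3 kept their call. A smaller share of cic mutant cells in cic than in cic wts discs could produce the pattern. The rises in cic discs were 0.29 (aos), 0.15 (pnt) and 0.15 (sty) of those in wts discs. The cic transcript fell 0.73 ± 0.27 (SE) times as much (20.5% against 28.2%). Set initially against the median of those 3 shares, 0.15, the test would exclude the explanation (2.13 standard errors). Set later against the highest, 0.29, it leaves it open (1.62), so the outcome depends on this choice. Of 13 Minute response genes 4 rose in cic discs, as it predicts, but 67 of 175 interaction genes changed more there. A changed response of Capicua targets after wts loss remains a hypothesis.

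The 8 ecdysone response genes that fell in wts discs were weighed against salivary gland RNA in control libraries and larval stage. Salivary gland RNA carried over in control libraries is argued against: 8 of 8 fallen members were higher in all 3 cic than in all 3 wts libraries at day 5, while Sgs3 in cic discs was 0.245% of its control mean. This test replaced an earlier one on salivary gland markers after the data were seen. An earlier larval stage of the wts larvae at day 5 may account for the pattern, since 4 of the 8 (Eip78C, br, ImpE2 and ImpE3) were called higher in wts discs at day 9, although leaving out 1 library ended the call in 5 of 6 fits for ImpE2 and Eip78C and in 3 for ImpE3; a direct effect of wts was not tested.

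The genes changed against control may partly reflect other differences between the stocks and pools. In cic discs 69.4% of called genes (95% interval 61.3 to 76.7, exact binomial) lay on arms 3L and 3R, against 43.9% of tested genes. Chromosome 3 of another strain could give this. The shares were 45.7% in wts (43.3 to 48.2) and 46.8% in cic wts discs (44.6 to 49). Their upper bounds, 1.097 and 1.115 times the tested share, lie just under and above the limit set. Chromosome 3 of another strain is thus argued against as the main source in wts discs only. Strain differences on other chromosomes were not tested, since these shares cover arms 3L and 3R alone. As few variants as in cic discs could stay hidden in either share. Arm 3R held in cic discs 32.7% against 24.2% (25.2 to 40.9), which decides nothing. Its shares of 24% in wts and 24.3% in cic wts discs argue against linked variants as the main source. For sex makeup, the criterion set before the data were examined was that roX1 and roX2 both differ by over 0.5 in the same direction, and it was met in all 3 comparisons: -0.62 and -0.70 in cic, 0.66 and 1.16 in wts, and 0.87 and 1.21 in cic wts discs, although neither RNA passed over all genes tested, and roX2 passed adjusted over the list alone in wts and cic wts discs. A second criterion, the calls kept with the roX level as a covariate, was added after the data were seen, and 79 of 147, 1013 of 1635 and 1310 of 2022 were kept; by the first criterion alone sex makeup could account for part of the pattern, by both together it stays open, and it was not excluded in any of the 3.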

How the results depend on the processing

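The roX covariate and the fit with control day 5 replicate 3 and cic wts day 5 replicate 1 left out together were chosen only after the results were seen. Of 299 gene results followed, 287 were called; 169 kept the call in every setting fixed beforehand, 108 lost it in a fit that lacked 1 library and 56 in another setting fixed beforehand. No direction turned except that of Hml in cic wts against control: leaving out each library gave -0.35 to 3.2, and leaving out both named libraries gave 0; the high library, cic wts replicate 1, is the one removed. With RLE size factors 299 results kept their side of the threshold, with total-count scaling 295, without the filter 292, with DESeq2 295 of 298, with only the libraries compared 244 and with the roX covariate 258 of 293.

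Counts of changed genes moved by over 1.5 times as follows, and the cause was not tested. DESeq2, whose simulated calls held more unchanged genes (10.8% against 1.39% with edgeR in cic against control, 11.4% against 4.35% for the interaction at day 5), called 251 in cic against control, 391 for the interaction at day 5, 478 in cic wts against wts at day 5, 32 for the interaction of cic with day and 1075 in wts day 9 against day 5. With only the libraries compared in the fit, which leaves fewer samples, the counts were 19 in cic against control, 1044 in cic wts against control, 78 for the interaction and 1031 in wts day 9 against day 5. The roX covariate gave 91 in cic against control and 1159 in wts day 9 against day 5, and leaving out both named libraries gave 403 in cic wts day 9 against day 5. Leaving out each library in turn gave 61 to 149 in cic against control, 813 to 1285 in wts against control, 92 to 257 for the interaction at day 5, 105 to 246 and 307 to 482 in cic wts against wts at day 5 and day 9, 118 to 467 in wts and 237 to 871 in cic wts day 9 against day 5. Of the 102 list calls, 0 held with an estimated correlation, and fry made 60. Leaving out 1 library turned the direction of 3 list tests: hemocytes in cic wts against wts at day 5 and for the interaction of cic with day (without cic wts day 5 replicate 1), and heat shock in cic against control (without control replicate 3). With 3 libraries a group, the simulated interaction recovered 23.9% of changes of 1.5 times, so smaller interactions were often not detectable at this depth and number of libraries.

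By the criterion that every pair with the same number correlate over 0.1, the replicate numbers were not taken to pair the libraries: 15 of 45 such pairs did (range -0.139 to 0.442). The median correlation was 0.054 for the same number and -0.0415 for other numbers, and 14 of 18 libraries correlated best with their own number, which is a hint from the data and not from the design. With the replicate block the counts were 108, 1653 and 2091 in cic, wts and cic wts against control, 165 for the interaction, 260 and 603 in cic wts against wts at day 5 and day 9, 631 and 965 for day 9 against day 5, 3 for the interaction of cic with day, and 104 list calls. Of the 299 gene results, 284 kept their side of the threshold and 15 lost the call (adjusted p from 0.051 to 0.15): pnt, Diap1, Gasp and Sgs7 in cic and Hml in cic wts against control, Stat92E, E(spl)m2-BFM, CycB3, Ama and CG4362 for the interaction, Mkp3 and dup in cic wts against wts at day 5, Mcm2 in wts and daw and PPO1 in cic wts day 9 against day 5.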

Other observations

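The tests on other splits of the libraries were planned. Some fixed gene lists are not described above. Of the 17 JNK and wound response genes, 6 rose, 1 fell and 10 did not pass (7 and 1 adjusted over the list alone, upward camera adjusted p = 0.0285, and adjusted p = 0.637 with an estimated correlation) in wts against control. In cic wts against control, 6 rose, 3 fell and 8 did not pass (6 and 3 adjusted over the list alone, camera adjusted p = 0.203). Of the 11 Toll and Imd immune genes, 0 rose, 0 fell and 11 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.369) in cic against control. Of the 10 germline genes, 3 rose, 0 fell and 7 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.207) in wts against control. Of the 9 neuron and glia genes, 0 rose, 0 fell and 9 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.388) in cic against control. Of the 9 tracheal genes, 2 rose, 2 fell and 5 did not pass (3 and 2 adjusted over the list alone, camera adjusted p = 0.607) in wts against control.

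Camera also called lists in comparisons not given above, each lost with an estimated correlation (adjusted p from 0.447 to 0.65); counts over all genes tested are followed by those adjusted over the list alone. In wts against control, cuticle genes were called downward (1 rose and 4 fell of 16, 1 and 5 alone, adjusted p = 0.0285). In cic wts against control, cuticle genes (1 rose and 7 fell of 16, 1 and 10 alone, adjusted p = 0.00175) and Wg pathway targets (1 rose and 5 fell of 10, 2 and 8 alone, adjusted p = 0.00835) were called downward, and polarity and junction genes upward (6 rose and 0 fell of 19, 9 and 0 alone, adjusted p = 0.011). In cic wts against wts at day 5, apoptosis genes (0 rose and 1 fell of 13, 0 and 1 alone, adjusted p = 0.0494), ecdysone response genes (0 rose and 2 fell of 21, 1 and 4 alone, adjusted p = 0.0236) and Wg pathway targets (0 rose and 2 fell of 10, 0 and 2 alone, adjusted p = 0.026) were called downward, and cell cycle genes upward (1 rose and 0 fell of 33, 1 and 0 alone, adjusted p = 0.0169). At day 9, Hippo pathway components were called downward (0 rose and 1 fell of 17, 0 and 3 alone, adjusted p = 0.0285). For the interaction at day 5, counted as positive and negative, retinal determination (0 positive and 1 negative of 12, 0 and 3 alone, adjusted p = 0.015) and secreted growth signal genes (1 positive and 3 negative of 22, 1 and 4 alone, adjusted p = 0.0171) were called downward, and ribosome biogenesis genes upward (0 positive and 0 negative of 19, 0 and 0 alone, adjusted p = 0.0105). Upward calls in wts day 9 against day 5 were Hippo pathway components (2 rose and 0 fell of 17, 4 and 0 alone, adjusted p = 0.0236), morphogen and patterning genes (2 rose and 1 fell of 37, 4 and 2 alone, adjusted p = 0.02), Ras/EGFR and Cic target genes (1 rose and 0 fell of 15, 1 and 0 alone, adjusted p = 0.0236) and Yki/Sd target genes (1 rose and 1 fell of 20, 5 and 1 alone, adjusted p = 0.0345), and in cic wts discs Ras/EGFR and Cic target genes (3 rose and 1 fell of 15, 5 and 1 alone, adjusted p = 0.0477).

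Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. In cic against control 2 of the 10 gave at least 147 genes, the highest other giving 257 with control replicates 1 and 2 and cic replicate 1 on one side, which points to a structure of these libraries apart from genotype. In the other 6 such comparisons 1 of 10, the real split, gave as many: 1635 in wts and 2022 in cic wts against control (highest others 0 and 1), 262 and 621 in cic wts against wts at day 5 and day 9 (1 and 0), and 620 in wts and 955 in cic wts day 9 against day 5 (0 and 1). For the interaction of cic with day, all 100 of 100 assignments gave at least the real count of 0 in edgeR (593 at an unadjusted p under 0.05, 32 with DESeq2), which any assignment reaches, so this test decides nothing; the highest other gave 1001. That assignment swaps the labels of both groups within 1 day, so that it tests the effect of cic summed over days.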
